A study of Mus musculus with 6 samples.

How the data were processed

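The deposited scanner files hold fluorescence intensities of 1-colour (Cy3) Agilent whole-genome mouse arrays, 1 array per sample, written by Feature Extraction 10.5.1.1 per the file headers. Per the file headers, the processed intensity of a spot is its signal after spatial detrending and background subtraction, with a surrogate value where a spot was not above background, and it was not normalized between arrays. The raw mean signal and the local background median of each spot were also read, as intensities without correction, together with the flags for well above background, outlier and saturated spots. Per the labels, RNA was extracted from dissected S1, amplified and labelled with Cy3 during in vitro transcription, and the mice were C57BL/6. The authors' series matrix holds log2 values for the same 55681 probes. Its processing is not given in the sources used here. Compared with the scanner files, it matches quantile-normalized log2 processed signals minus each probe's median over the 6 arrays, with 95% of values within 0.00235. The column medians lie between -0.0064 and 0.00645. Its scale and centring are inferred from the values, and it was used as an alternative.

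The values tested here were log2 processed signals minus each array's 75th percentile. Control spots and outlier-flagged spots (112 to 198 per array) were left out, and spots of 1 probe were averaged, with a median coefficient of variation between 5.92% and 8.34% for probes spotted repeatedly. A probe was tested if it was well above background on at least 3 of the 6 arrays, in whichever group. Each gene took its probe with the highest mean over the 6 arrays. Gene names were updated through a RefSeq gene table of assembly GRCm38.p6, used only for names and gene order: 28331 probes matched by accession, 253 by another accession in the same row, 2209 by symbol and 162 by synonym, while 24726 kept the name in the file. Probe coordinates are those of the files, on mm9, and were not converted. No reference genome was used here.

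The groups were compared with limma (R 4.3.3, limma 3.58.1), by lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all 32697 genes and a threshold of 0.05 on the adjusted p. Fold changes are 2 to the power of the log2 difference. Gene lists for cortical layers, areal patterning, guidance, receptors, cell types, neighbouring tissues and metabolic or stress programmes were fixed in number (35) and content before the data were examined, as were the tests and the other ways of processing. Lhx2 and Neurod6 were left out of every list. The 34 lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated per list and with fry. The list of sex-linked genes had fewer tested members and is given as values. Members were also counted with p adjusted over the list alone. The genes named are Lhx2 and Neurod6; up to 12 genes per direction with the most extreme log2 difference among those that passed, without clone, Gm or LOC names; where fewer than 5 passed, also the 10 genes with the smallest p, as values; and up to 4 members per list with the smallest p, given as values where they did not pass; the members of a list with no called member could be left to the count, and some are named. Any other gene named was chosen after its values were seen.

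The fit was tested in 5 runs on simulated arrays with the means of the 32697 genes and spreads drawn from the fitted distribution of variances. Over the runs, 335 genes were changed by each amount. The simulated arrays held no differences by slide row or sex, so the rates may not hold for the real arrays. At an adjusted p under 0.05 it recovered 1.19% of genes changed by 0.5 on the log2 scale, 52.8% of those changed by 1 and 91.6% of those changed by 2. Over the 5 runs these were 4, 177 and 307 genes, whereas the real comparison called 3 genes. With fewer genes called, the adjustment demands a smaller unadjusted p. The rates are therefore not the power of the real comparison and may be too high for it. In simulated lists shifted by 0.4, camera called 25 of 25 shifted lists and 0 of 70 others, with genes drawn independently.

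The other ways of processing were quantile normalization, median centring, normexp background correction with an offset of 50 under either scaling, no filter on dim probes, a filter on all 6 arrays, outlier-flagged spots kept, the mean of a gene's probes, an intensity trend with robust variances, array weights, the replicate number as a block, each array left out in turn, the authors' matrix, other thresholds and other set tests. Terms for the row of the slide and for Y-linked signal, and a comparison without the 2 arrays with Y-linked signal, were added after seeing the data. Those 2 arrays were found from the mean of the probes of Ddx3y, Eif2s3y and Kdm5d, genes picked after their values were seen; Uty was not used. A slide or scan block was not run because there was 1 slide and 1 scan.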

Results

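Gene expression was measured in total RNA of the primary somatosensory cortex (S1, the area that receives touch input from the body and whiskers) of mice at postnatal day 7, with 1 single-colour array per sample. The control group held 3 samples with floxed Lhx2 alleles and no Cre. The cKO group held 3 samples in which Nex-Cre, a Cre recombinase knocked into the Neurod6 (Nex) gene and active in young excitatory neurons of the cortex, was combined with the floxed alleles. Lhx2 encodes a LIM-homeodomain transcription factor. The labels do not say whether the samples of a group came from separate animals, so p-values measure only the spread between these samples. Each array carried 62976 spots, of which 59305 were not controls and stood for 55681 probes. Between 86.7% and 91.1% of these spots were well above background and 0 were saturated. The 75th percentile of the processed signal ranged from 892 to 1067 intensity units. After the filter on dim probes, 50029 probes standing for 32697 genes were tested. The number of arrays limits the precision of every value below.

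The first question was whether the targeted gene and the Cre locus differed between the groups. The Lhx2 probe (chromosome 2, 38224933 to 38224992 on mm9) gave more signal in all 3 arrays labelled cKO than in any control array, at 4.71 ± 0.17 against 3.60 ± 0.04 (log2 signal relative to the array's 75th percentile, mean ± SD, n = 3 each). This is a 2.15-fold higher signal (log2 difference 1.1, SE 0.11), with an adjusted p of 0.067 that did not pass the threshold over all genes. Which part of Lhx2 the floxed alleles lose is not given in the sources used here, and a probe outside the deleted part checks nothing. The direction is nevertheless opposite to a loss of transcript, so the samples are called the arrays labelled cKO throughout, and every direction below rests on the labels. The Neurod6 probe (chromosome 6, 55628006 to 55628065) read 2.62 ± 0.20 in the arrays labelled cKO and 2.25 ± 0.11 in control, a log2 difference of 0.37 with an adjusted p of 0.52. It was higher in 3 of 3 arrays labelled cKO than in every control array. A Cre carrier was expected to have fewer intact copies of Neurod6, so this planned check of the labels also went against the expected direction. Where the probe lies relative to the insertion was not worked out. Gm3279, a long non-coding RNA gene that follows Neurod6 in the reference gene order, had the most extreme difference among the genes that passed. Its probe (chromosome 6, 55644473 to 55644532) lies 16.4 kb from the Neurod6 probe and read -1.04 ± 0.14 in the arrays labelled cKO against -5.39 ± 0.54 in control, which is 20.4-fold higher (log2 difference 4.35, adjusted p = 0.027, higher in 3 of 3 arrays). The size depends on how the dim control signal is treated: with normexp background correction the log2 difference of Gm3279 was 2.61 or 2.58, by scaling, and it still passed. Gm3279 lies outside the naming rule and was chosen after its values were seen. Exon and UTR annotation on mm9 was not used here.

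**Figure D1:**
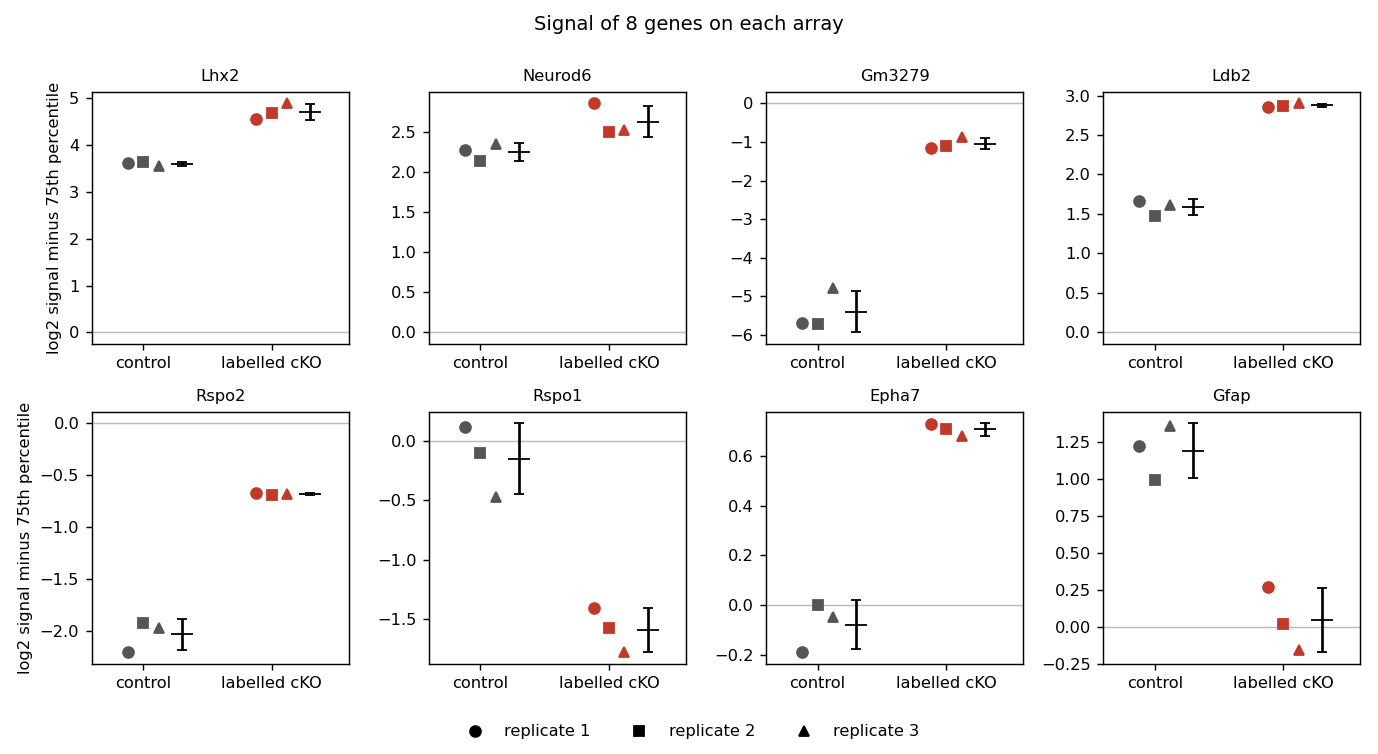
Log2 signal minus the array's 75th percentile (vertical axis, own scale per panel) of 8 genes on the 3 control arrays (grey) and the 3 arrays labelled cKO (red); symbols mark the replicate number and the bars the mean ± SD. Lhx2 read 4.71 on average in the arrays labelled cKO and 3.60 in control, and Gm3279 -1.04 against -5.39, with no overlap between the groups.

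The arrays also differed in ways that the genotype labels do not give. The Ddx3y probe, on the Y chromosome, read 1.04 and 0.89 in control replicates 1 and 3, and was not well above background in control replicate 2 or in any array labelled cKO. Eif2s3y, also on the Y chromosome, read 2.01 and 1.78 in the same 2 arrays and was not well above background in the other 4. The more discriminating Xist probe read between 0.72 and 1.13 in the 4 arrays without Y-linked signal and was not well above background in the other 2. Of the Y-linked gene Uty, 1 dim probe was also well above background in cKO replicates 1 and 3, at -5.13 and -5.58, against -3.82 and -3.66 in control replicates 1 and 3. By Ddx3y, Eif2s3y and Kdm5d, sex differed between the groups, with Y-linked signal in 2 of 3 control arrays and 0 of 3 arrays labelled cKO. All 6 arrays lay on 1 slide and were scanned once, in 4 rows. The first principal component, with 33.8% of the variance, followed the row (Pearson r = -0.94, exact permutation p = 0.011; Spearman rho = -0.97, exact permutation p = 0.011; 6 arrays, 1 relation computed). Without cKO replicates 1 and 2, r was -0.97. Replicate 1 lay farthest from the median row and replicate 2 was 1 of several tied at the next distance. Other pairs were not left out. The second principal component, with 23.2% of the variance, lay between -23.4 and -11.8 in the arrays labelled cKO and between 14 and 26.9 in control. This separation of the groups was not tested. Row 1 held control replicate 1 and cKO replicate 2, and row 2 held control replicate 2 and cKO replicate 3. These rows allow a comparison within a row, of 1 array with 1. In both rows the cKO array lay in slide column 2 and the control array in column 1. In row 1 the arrays also differed in Y-linked signal. The values within rows given below therefore cannot separate the group from the column, nor in row 1 from Y-linked signal.

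Across all genes, 3 rose in the arrays labelled cKO and 0 fell. Besides Gm3279 these were Ldb2, a cofactor that binds LIM-domain proteins, which was 2.45-fold higher (log2 difference 1.29, SE 0.09, adjusted p = 0.042), and Rspo2, a secreted activator of Wnt signalling, which was 2.55-fold higher (log2 difference 1.35, SE 0.10, adjusted p = 0.049). Each was higher in 3 of 3 arrays than in every control array. The next genes by p did not pass, with adjusted p between 0.055 and 0.057. Among them, the log2 difference was 2.04 for Tacr1, the receptor of substance P, 1.21 for the neuropeptide gene Grp and 1.01 for Dact1, a regulator of Wnt signalling. It was -2.12 for Rgs13, a regulator of G-protein signalling, -1.27 for the phosphodiesterase gene Pde8b, -1.43 for the phospholipase gene Plb1 and -1.94 for Dock5. The other tested probes of Plb1 read 0.21 and 0.14, and the other probe of Pde8b -0.38, so these genes rest on their brightest probe. By limma, 2451 genes had an unadjusted p under 0.05, 1021 of them higher and 1430 lower. The values of the 2 groups did not overlap for 13.2% of genes, where chance gives 10%.

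The count depended on single arrays and on the scaling. Without replicate 1, 2 or 3 of the arrays labelled cKO, 0, 1 and 0 genes passed, and the 1 gene was lower and not among the 3. Without control replicate 1, 2 or 3, the counts were 2, 4 and 4, of which 0, 2 and 3 were lower and 1 each was among the 3. Quantile normalization called 12 genes (8 higher, 4 lower), median centring 24 (14 higher, 10 lower) and normexp background correction 89 (42 higher, 47 lower). A term for the slide row or for Y-linked signal, added after seeing the data, left 0 genes, and the comparison without the 2 arrays with Y-linked signal left 1. With the linear row term the log2 differences stayed at 4.32 for Gm3279 (SE 0.26, before 4.35, SE 0.26), 1.30 for Ldb2 (SE 0.08, before 1.29, SE 0.09) and 1.34 for Rspo2 (SE 0.10, before 1.35, SE 0.10). Their adjusted p was 0.051, with 3 residual degrees of freedom in place of 4. With the term for Y-linked signal they were 4.66 (SE 0.35), 1.40 (SE 0.14) and 1.24 (SE 0.15), so the calls ended with larger errors. Some dim genes named here shrank with normexp, to -1.23 for Rgs13, -0.17 for Ptgs2, 0.42 for Lhx5, -0.44 for Htr2b and -0.35 for Oasl2 at the smallest. Others shrank when a gene's probes were averaged, to -0.36 for Plb1, -0.83 for Pde8b, 0.08 for Fosl2, 0.37 for Nrp2 and 0.22 for Pcdh15.

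Genes of the cortical layers were compared next, in lists fixed for S1. Markers of layer 4, the main target of thalamic input, fell as a list (12 tested, median log2 difference -0.47; 9 lower and 3 higher by sign; camera adjusted p = 1.18e-05, and adjusted p = 0.29 with an estimated correlation). With p adjusted over the list alone, 4 members fell: Rspo1 by 1.44 on the log2 scale (2.71-fold lower), the potassium channel subunit genes Kcnab3 by 1.07 and Kcnh5 by 1.11, and the sodium channel subunit gene Scnn1a by 0.59. None of these passed over all genes, where the lowest adjusted p was 0.079, for Rspo1. Each was lower in 3 of 3 arrays than in every control array. Kcnab3 and Kcnh5 are also in the longer potassium channel list, where neither passed with p adjusted over that list. Within slide row 1 the layer 4 list's median was -0.42 and within row 2 -0.62. Against control replicate 2 alone, the control without Y-linked signal, it was -0.66. Control replicate 3 was in none of these comparisons. Relative to the control mean, its layer 4 median was -0.22, near cKO replicates 2 (-0.32) and 3 (-0.33). In cKO replicate 1 it was -0.62, and in control replicates 1 and 2 it was 0.11 and 0.08. Astrocyte, oligodendrocyte and microglial markers, given below, fell in the same arrays.

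Layer 5 markers went both ways. With p adjusted over the list alone, 5 of 20 rose and 3 fell, and over all genes only Ldb2 passed. The members with the smallest p after Ldb2 were Tcerg1l, with a log2 difference of 1.09, Bcl6, a transcriptional repressor, with -1.0, and Sulf2, a sulfatase gene, with 0.59. The list as a whole was not called (camera adjusted p = 0.84), and its median of -0.10 and the direction of its test differ in sign. Of 18 layer 6 markers, 1 rose with p adjusted over the list alone: Rprm, by a log2 difference of 0.83 (adjusted p = 0.097 over all genes). Of 20 layer 2/3 markers, 1 fell in that adjustment: Kitl, the ligand of the receptor Kit, at -0.69. Cux1 (-0.52) and Cdh13 (1.03) did not pass. Neither the layer 6 nor the layer 2/3 list was called, with a camera adjusted p of 0.28 for each. Subplate markers fell as a list (15 tested, median -0.18, camera adjusted p = 0.026, and adjusted p = 0.35 with an estimated correlation). With p adjusted over the list alone, 2 of them fell, Cplx3 by 0.43 and the dopamine receptor gene Drd1 by 0.44. The subplate median relative to the control mean was -0.29 and -0.13 in cKO replicates 2 and 3. In cKO replicate 1 it was 0.10, above every control array. The subplate call was lost in several refits, among them those without cKO replicate 2 (median -0.10) or 3 (-0.11), without control replicate 1 (-0.17) and with the term for Y-linked signal (-0.18).

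**Figure D2:**
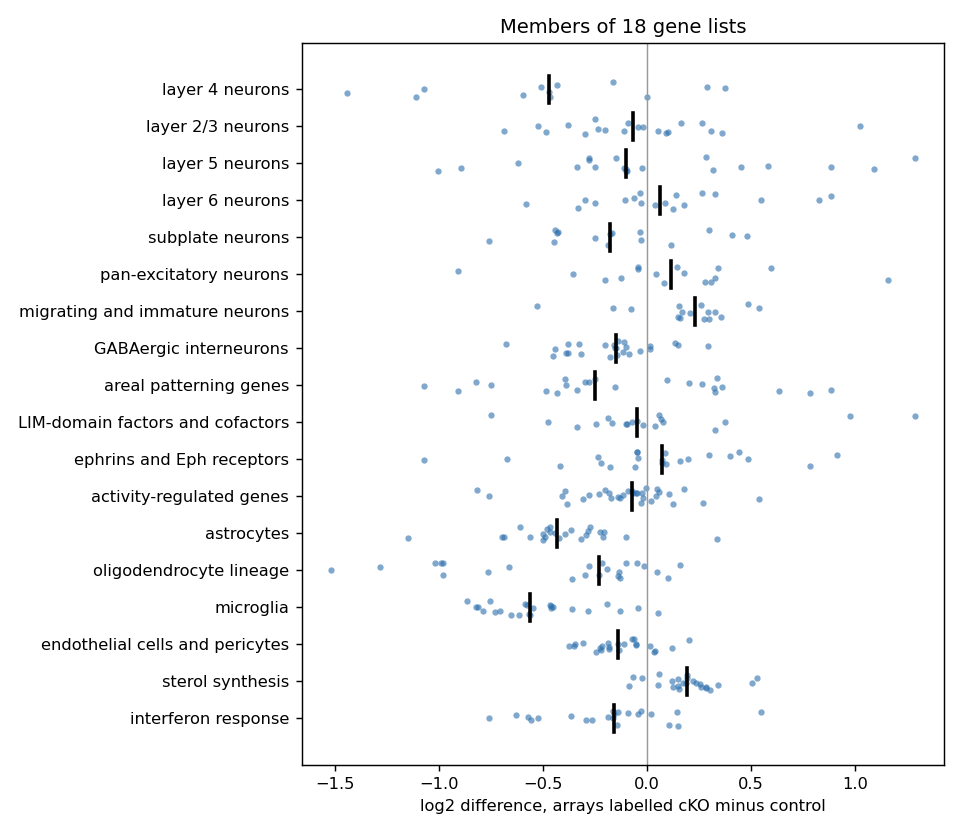
Log2 difference between the arrays labelled cKO and control (horizontal axis) for each tested member of 18 gene lists fixed beforehand; points are genes, each the difference of 2 means of 3 arrays, and black bars are list medians. The medians were -0.47 for layer 4, -0.43 for astrocytes and -0.56 for microglia, and 0.19 for sterol synthesis.

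Genes that pattern cortical areas and guide axons changed in both directions. Of 23 areal patterning genes, 7 rose and 6 fell with p adjusted over the list alone, 0 passed over all genes, and the list as a whole was not called (camera adjusted p = 0.48). Epha7, a receptor for ephrins, was 1.72-fold higher (log2 difference 0.78, SE 0.09, adjusted p = 0.071 over all genes), and its other 2 probes gave 0.74 and 0.93. Its ligand gene Efna5 was lower, with a log2 difference of -1.07, as were the transcription factor gene Emx1 at -0.91 and the LIM-only gene Lmo3 at -0.75. Among 22 ephrins and Eph receptors, 3 rose (Epha7, Epha6 at 0.92 and Efnb2 at 0.40) and 1 fell (Efna5) with p adjusted over the list alone. Of 28 genes linked to barrels and thalamic axons, 21 of them also in another list, 1 rose (Epha7) and 1 fell (Efna5) in that adjustment. Of 19 LIM-domain factors and cofactors other than Lhx2, 3 rose, Ldb2, Lhx5 (0.98) and Ssbp2 (0.37), and 2 fell, Lmo3 and Lmo4 (-0.33). The barrel, LIM-domain and Eph lists were not called, with camera adjusted p of 0.84, 0.86 and 0.24.

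Among 36 cadherins outside the protocadherin clusters, 7 rose and 1 fell with p adjusted over the list alone. Pcdh20 fell by 0.93, while Cdh10 rose by a log2 difference of 0.54, Fat1 by 0.47 and Pcdh15 by 0.36. Among 48 semaphorins, netrins, slits and their receptors, 2 rose, Robo1 (0.78) and Nrp2 (0.63), and 1 fell, Plxnb3 (-1.12). The camera adjusted p was 0.097 for the cadherins and 0.59 for the guidance genes.

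Glial genes were lower. Astrocyte markers fell as a list (24 tested, 23 lower, median log2 difference -0.43, camera adjusted p = 3.47e-17, and adjusted p = 0.18 with an estimated correlation). With p adjusted over the list alone, 15 fell and 1, Hes5, rose. Gfap, the intermediate filament of astrocytes, was 2.22-fold lower (log2 difference -1.15, SE 0.15, adjusted p = 0.089 over all genes), the water channel gene Aqp4 differed by -0.46, Ndrg2 by -0.42 and the glutamine synthetase gene Glul by -0.61. Genes of the oligodendrocyte lineage fell as well (23 tested, 20 lower, median -0.23, camera adjusted p = 7.60e-10, and adjusted p = 0.18 with an estimated correlation). With the mean of all tested probes of a gene the oligodendrocyte lineage median was -0.36. In the adjustment over the list alone, 7 fell, among them the myelin enzyme gene Cnp by 0.98, Enpp6 by 1.52, Bcas1 by 0.99 and the receptor gene Gpr17 by 0.66. Microglial genes fell (24 tested, 23 lower, median -0.56, camera adjusted p = 8.18e-17, and adjusted p = 0.27 with an estimated correlation), 12 of them with p adjusted over the list alone, including the fractalkine receptor gene Cx3cr1 by 0.82, the complement genes C1qb by 0.58 and C1qc by 0.81, and Tyrobp by 0.79. No glial gene passed over all genes.

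These 3 lists were lower on each of the arrays labelled cKO than on every control array. The medians relative to the control mean lay between -0.51 and -0.37 for astrocytes, -0.33 and -0.22 for the oligodendrocyte lineage, and -0.86 and -0.23 for microglia. Within slide row 1 the differences were -0.35, -0.29 and -0.63, and within row 2 -0.50, -0.33 and -0.90. Against control replicate 2 alone they were -0.45, -0.31 and -0.64. By fry, which tests whether a list's genes move on balance one way, the astrocyte and oligodendrocyte lists passed among the 34 lists (adjusted p = 0.032 each), and the microglial list did not (0.12).

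**Figure D3:**
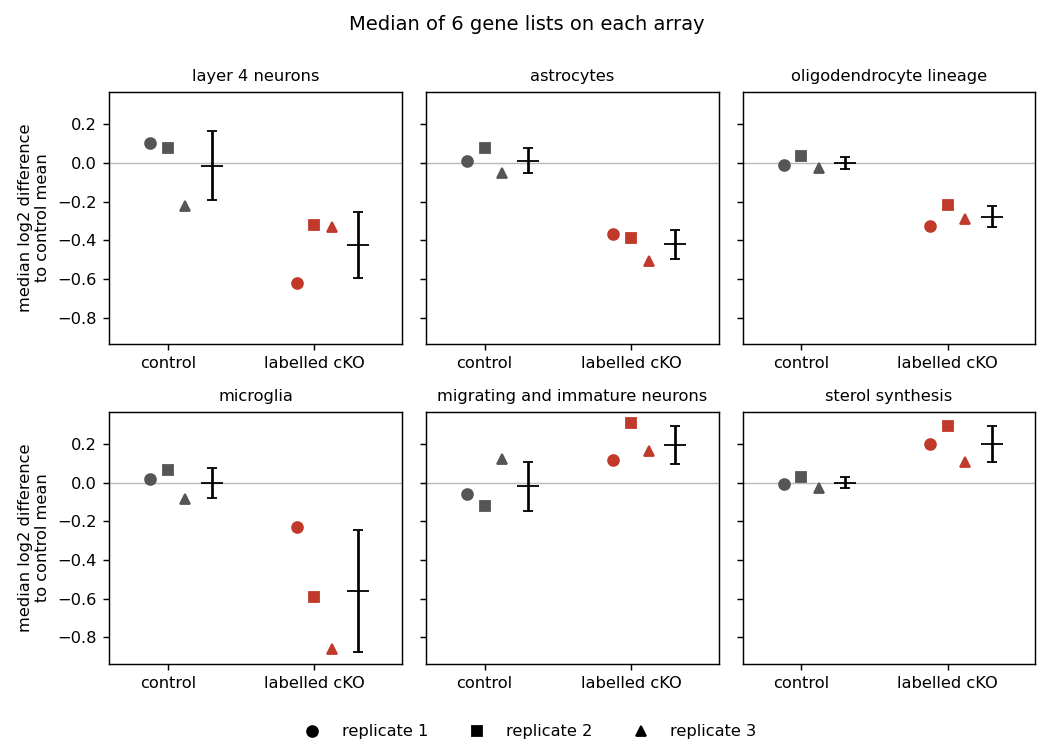
Median over the members of 6 gene lists of the log2 difference to the control mean (vertical axis) on each control array (grey) and each array labelled cKO (red); symbols mark the replicate number and the bars the mean ± SD of 3 arrays. Astrocyte medians lay between -0.51 and -0.37 in the arrays labelled cKO and between -0.05 and 0.08 in control.

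Genes of young neurons and of sterol synthesis were higher. Markers of migrating and immature neurons rose as a list (16 tested, 13 higher, median log2 difference 0.23, camera adjusted p = 1.78e-04, and adjusted p = 0.30 with an estimated correlation), although 0 of them passed with p adjusted over the list alone. The smallest p belonged to the growth-associated genes Marcksl1 (0.36) and Gap43 (0.30) and the tubulin-binding protein gene Stmn1 (0.33). Astrocyte, oligodendrocyte and microglial markers fell in the same arrays. Control replicate 3, at 0.13, lay within the range of the arrays labelled cKO for this list. Sterol synthesis genes rose (24 tested, 21 higher, median 0.19, camera adjusted p = 2.24e-08, and adjusted p = 0.29 with an estimated correlation). Fdps, which makes farnesyl diphosphate, rose by a log2 difference of 0.51 with p adjusted over the list alone. Within slide rows 1 and 2 the sterol median was 0.29 and 0.10, and that of the immature neuron list 0.28 and 0.30.

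General neuron genes gave a mixed result. Of 16 genes shared by excitatory neurons, Neurod1 rose (log2 difference 1.16) and Emx1 fell with p adjusted over the list alone, and the list was not called (median 0.12, camera adjusted p = 0.15). GABAergic interneuron genes fell as a list (25 tested, 20 lower, median -0.15, camera adjusted p = 0.0015, and adjusted p = 0.27 with an estimated correlation) with 0 members past the threshold with p adjusted over the list alone. The median was -0.10 without control replicate 3. Gad2, which makes GABA, differed by -0.38 and Npy by -0.45. Activity-regulated genes fell as a list (32 tested, median -0.07, camera adjusted p = 0.036, and adjusted p = 0.35 with an estimated correlation). Their median relative to the control mean was -0.09 and -0.13 in cKO replicates 2 and 3. In cKO replicate 1 it was 0.04, above every control array. In the adjustment over the list alone Ptgs2 fell by 0.82, Ccn1 by 0.39 and Rgs2 by 0.38, and Fosl2 rose by a log2 difference of 0.54. Ptgs2 was well above background on 1 of 3 arrays labelled cKO, and the other probe of Fosl2 gave -0.38. The call on activity-regulated genes was lost in several refits, among them those without cKO replicate 2 (median -0.06) or 3 (-0.05), without control replicate 1 (-0.05) or 2 (-0.09), and with the term for Y-linked signal (-0.06). Of 21 neuropeptide genes, Grp rose with p adjusted over the list alone, and the list was not called (camera adjusted p = 0.060). It passed as lower in 8 of 22 refits, among them those with the slide row as a linear term or a block, and its median ranged from -0.40 to -0.03. Among 28 serotonin and monoamine genes, Htr2b (-0.84) and Drd1 fell in that adjustment. No gene passed among 25 glutamate receptors, 15 GABA-A receptor subunits or 36 voltage-gated potassium channels, with camera adjusted p of 0.43, 0.84 and 0.28. Kcnab3 and Kcnh5, called in the shorter layer 4 list, are among these potassium channels. The potassium channel list passed as lower in 6 of 22 refits, such as those with the term for Y-linked signal (adjusted p = 0.046) and with the slide row as a block (0.0072). The GABA-A list passed as lower in 2, and the glutamate receptor list as higher in 1. Cadherins and genes shared by excitatory neurons passed as higher in 3 each, and layer 2/3 markers as lower in 1.

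Interferon genes were lower on each of the arrays labelled cKO, while several lists for neighbouring tissue depended on single arrays. Interferon response genes fell as a list (22 tested, median -0.16, camera adjusted p = 5.82e-04, and adjusted p = 0.27 with an estimated correlation), with Oasl2 at -0.76 and Xaf1 at -0.63, neither past the threshold. The interferon median was -0.07 without cKO replicate 2 and -0.10 with normexp background correction and the 75th percentile. The glial lists fell in the same arrays as the interferon and GABAergic interneuron lists. The subplate list fell in cKO replicates 2 and 3 alone. Endothelial and pericyte genes fell by a median of 0.14 (23 tested, camera adjusted p = 0.0019, and adjusted p = 0.49 with an estimated correlation), and the call was lost without cKO replicate 2 (median -0.10), without control replicate 1 (-0.05) and with the term for Y-linked signal (-0.08). The meninges list (18 tested, median -0.35, camera adjusted p = 0.0035, and adjusted p = 0.63 with an estimated correlation) had medians of -1.16 in cKO replicate 2 and 0.25 in cKO replicate 3, and a median of 0.07 without the former. It also lost its call in other refits, such as those without control replicate 1 (median -0.23) and with the term for Y-linked signal (-0.003). The striatum list (18 tested, median -0.21, camera adjusted p = 0.0019, and adjusted p = 0.48 with an estimated correlation) and the progenitor list (27 tested, median -0.29, camera adjusted p = 3.67e-06, and adjusted p = 0.50 with an estimated correlation) were highest in control replicate 3, at 0.52 and 0.33 above the control mean. Without it the striatum call was lost (median 0.02), while the progenitor list kept its call at a median of -0.11. With the term for Y-linked signal both were lost, at -0.04 and -0.09. The slide row as a block also ended both calls, at -0.06 and -0.07. In the striatum list Drd1 fell with p adjusted over the list alone. The thalamus list fell (14 tested, median -0.09, camera adjusted p = 0.021, and adjusted p = 0.27 with an estimated correlation) and lost its call without cKO replicate 2 (-0.06), without control replicate 1 (-0.14) and with the term for Y-linked signal (-0.07). Blood genes, which include near-identical globin copies, rose as a list (14 tested, median 0.27, camera adjusted p = 0.043, and adjusted p = 0.63 with an estimated correlation), with medians of 0.71 in cKO replicates 1 and 2 and -0.21 in cKO replicate 3. The blood call held in 9 of 22 refits and was lost, for example, without cKO replicate 1 (0.10) or 2 (0.16), without control replicate 1 (0.27) or 3 (0.08), and with the term for Y-linked signal (-0.07). Over the 22 refits the medians ranged from -0.14 to 0.77 for blood and from -0.24 to -0.05 for endothelial and pericyte genes. They ranged from -0.38 to 0.02 for the striatum list and from -0.26 to -0.05 for the thalamus list. Choroid plexus, hippocampal and stress genes were not called, with camera adjusted p of 0.17, 0.35 and 0.86. Of the hippocampal genes, Lefty1 fell by 0.63 with p adjusted over the list alone. In all, 16 of 34 lists passed by camera with its preset correlation, 13 lower and 3 higher. With an estimated correlation 0 passed after adjustment, and 6 had an unadjusted p under 0.05.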

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

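The terms for slide row and Y-linked signal and the comparison without the 2 arrays with Y-linked signal were chosen after seeing the data. Against 3 genes (3 higher, 0 lower) in the reported comparison, quantile normalization and the authors' matrix each gave 12 (8 higher, 4 lower), median centring 24 (14 and 10), normexp with the 75th percentile 89 (42 and 47), normexp with quantile normalization 75 (40 and 35), a filter on all 6 arrays 13 (8 and 5), an intensity trend with robust variances 110 (55 and 55), array weights 168 (68 and 100), and an adjusted p under 0.10 gave 86 (39 and 47). All 3 genes were among the calls in each of these. Counting probes gave 1. Limma called 0 genes (0 higher) without a filter on dim probes, with the replicate block, with the slide row as a linear term, with it as a block, and with the term for Y-linked signal; in the same order, 2867, 2236, 3273, 3456 and 1098 genes had an unadjusted p under 0.05. Without the 2 arrays with Y-linked signal, where the lone control is assumed to vary like the other group, 1 gene passed (1 higher). Leaving out each array in turn gave 0 to 4 genes, 0 to 2 higher and 0 to 3 lower. Keeping outlier-flagged spots, averaging probes and a minimum log2 difference of 0.58 left the counts within 1.5 times. Arrays with the same replicate number showed no clear pairing. Their deviations from the group means correlated by -0.20, 0.08 and 0.17 for numbers 1, 2 and 3, and 3 of 6 arrays correlated best with their own number. With 3 arrays per group, which also differ in slide row, this check cannot decide whether a number marks a shared litter or day. Lhx2 stayed higher in the arrays labelled cKO everywhere, from 1.01 to 1.18 with each array left out, and passed the threshold with normexp and the 75th percentile (1.1), normexp and quantile normalization (1.07), the filter on all 6 arrays (1.1), the intensity trend (1.1) and array weights (1.16); its adjusted p ranged from 0.0042 to 0.31 over the planned full-array refits. Neurod6 never passed and ranged from 0.26 to 0.44 with each array left out. Against 16 lists past the threshold, there were 0 with an estimated correlation (lowest adjusted p = 0.18), 2 with fry, 9 with the term for Y-linked signal (8 of the 16), 10 without those 2 arrays (9 of the 16), and 12 to 17 with each array left out (10 to 15 of the 16). Over 22 refits with camera, 8 lists passed in every one, though not with the same median: layer 4, astrocytes, oligodendrocyte lineage, microglia, GABAergic interneurons, immature neurons, sterol synthesis and interferon response. Of these refits 1, the intensity trend with robust variances, cannot change a camera result and adds no support. The blood list turned negative with array weights (-0.14) and with the slide row as a block (-0.0511), and the meninges list positive without cKO replicate 2 (0.0721), while it was -0.69 without cKO replicate 3. The slide or scan block was not run, since there was 1 slide and 1 scan. The causes of these differences were not tested. Signal over background limits dim probes, and 86.7% to 91.1% of spots were well above it.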

Other observations

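Of the tests reported here, those of exchanged arrays, exchanged groups, slide row, sex, cell share and a strain segment were chosen after the result was seen, as were the genes named outside the lists. Of the 86 genes with an adjusted p under 0.10 (39 higher, 47 lower), 3 had passed the threshold of 0.05. Those named next had not, and whether they share a function was not tested. Aldh1a3, a retinoic acid synthesising enzyme gene, was 15.2-fold higher in the arrays labelled cKO (log2 difference 3.93, adjusted p = 0.070), and Glp2r, a peptide hormone receptor gene, was 7.98-fold lower (log2 difference -3.0, adjusted p = 0.071). The control signal of Aldh1a3 was dim (mean -4.82), near that of Gm3279 (-5.39), whose difference shrank with normexp background correction. The size of the Aldh1a3 difference under that correction is not given here. The growth factor gene Bmp2 differed by -1.67, Vegfd by 1.28, the secreted peptide gene Ostn by -2.26, the vasopressin receptor gene Avpr1a by 1.55, and the chromatin organiser gene Satb1 by -1.24. Of the R-spondin genes, secreted activators of Wnt signalling, Rspo2 had passed the threshold of 0.05, with a log2 difference of 1.35. Rspo1 (-1.44, adjusted p = 0.079), Rspo3 (-1.25, adjusted p = 0.18) and Rspo4 (-0.05) did not pass. Whether these genes differ from each other was not tested.

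By fry's test for change in either direction, which does not compare a list with other genes, 23 of 34 lists passed. Layer 5 markers and neuropeptides had the lowest adjusted p (1.12e-05 each), while their directional tests did not pass (0.44 and 0.84). In the layer 5 list Ldb2, Tcerg1l and Crym had log2 differences of 1.29, 1.09 and 0.89, and Bcl6 and Diaph3 of -1.0 and -0.62.

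The Lhx2 probe gave more signal in the arrays labelled cKO (log2 difference 1.1). An exchange of 1 array of each group is argued against by Lhx2, named before the values were seen: the lowest array labelled cKO lay above the highest control by 0.92 (SD within groups 0.12). Neurod6, the other check named beforehand, was also higher in each array labelled cKO, but its gap of 0.15 (SD within groups 0.16) cannot decide. An exchange of the whole groups' labels and the reading of transcript from a recombined allele by a probe outside the deleted part cannot be told apart, because the deleted part is not given in the sources used here. A higher output of the recombined locus, a biological explanation, stays open and untested. All signed values in the report would turn with exchanged labels.

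Gm3279 was 20.4-fold higher in the arrays labelled cKO (log2 difference 4.35, and 2.58 with normexp background correction and quantile normalization), 16.4 kb from the Neurod6 probe where Nex-Cre is inserted. A candidate explanation is a segment of another strain carried along with the Nex-Cre allele. Within 5 Mb of Neurod6, 10.4% of 115 other genes had an unadjusted p under 0.05 (exact binomial 95% interval 5.51% to 17.5%), against 7.51% of 31311 genes elsewhere (Fisher's exact test p = 0.22, two-sided; genes are not independent), which leaves a wide segment open. The nearest other gene with a known name, Adcyap1r1, differed by -0.26 (adjusted p = 0.56). An effect of the inserted allele on its neighbour, tied to the genotype, was not tested and may equally account for the signal.

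The astrocyte, oligodendrocyte and microglial lists (71 members, of which 1 astrocyte marker is also in another list) were lower in the arrays labelled cKO. A linear trend over the rows of the slide as the whole cause is argued against by the per-array glial medians: with the row as a linear term the groups differed by -0.413 (95% confidence interval between arrays -0.66 to -0.17, 6 arrays, 3 residual degrees of freedom), and by -0.407 without it. The slide column was not tested, and cKO replicates 2 and 3 lay in another column than the controls. Replicate 1 lay in the controls' column with a glial median of -0.311, against -0.063 to 0.054 in the controls, which goes against the column as the whole cause but is 1 array, so the column stays open. For sex, the control without Y-linked signal lay 0.0810 above the 2 controls with it, but as 1 array it cannot decide, so sex and genotype cannot be told apart here. A smaller share of all non-neuronal cells predicts an equal fall of endothelial and pericyte genes; the glial median differed from the endothelial one by -0.32, yet glial minus endothelial medians nearly met between cKO replicate 2 (-0.16) and control replicate 1 (-0.15), so this stays open. Fewer or less mature glia in the cKO is a hypothesis that these bulk values do not separate from the former, and it was not tested.

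For the count of genes, 10 splits of the 6 arrays into 3 and 3 exist, too few for a share under 0.05. The real split gave 3 genes and the highest other also 3, so 2 of the 10 splits gave as many. That other split set cKO replicates 1 and 3 with control replicate 3 against the arrays of row 1 and control replicate 2, follows the first principal component and the slide rows, and had 4890 genes with an unadjusted p under 0.05 against 2451 for the real split, which points to a structure of the arrays along the slide. With the slide row as a linear term 0 genes passed, but the log2 differences of the 3 genes hardly moved: 4.32 for Gm3279 (SE 0.26, before 4.35, SE 0.26), 1.30 for Ldb2 (SE 0.08, before 1.29, SE 0.09) and 1.34 for Rspo2 (SE 0.10, before 1.35, SE 0.10). The calls ended at an adjusted p of 0.051, with 3 residual degrees of freedom in place of 4. For the lists, the real split gave 16 and the others 5 to 17, and 3 of the 10 splits gave as many. Camera with its preset correlation thus called lists in every split of these arrays. The number of lists called does not set the real split apart.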
